A study of Mus musculus with 4 samples.

How the data were processed

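RNA of mouse peritoneal macrophages was hybridised to a 1-colour whole-transcript array after biotin labelling, per the labels' protocols. The deposited values are log2 expression values with 2 decimals, 1 column per array; the submitters' processing notes name RMA and Affymetrix Expression Console 1.4. Values run from 1.42 to 19.85, and between 255 and 268 probe sets per array lie above 16, the log2 limit of a 16-bit scanner, so a rescaling beyond the usual steps cannot be excluded and its nature is not given in the sources used here. Differences between arrays are therefore given on the deposited log2 scale. Detection calls were not used here, and the genome build is not given in the sources used here, so no coordinates are printed.

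Samples were grouped by their titles into control and supernatant, with 2 biological replicates each. The labels call the replicates biological and do not say whether a number marks shared animals or a shared day. Each probe set was named through the platform annotation: 19572 had 1 symbol, 0 had several and 2634 were not named here. All 19572 gene identifiers were found with the same symbol in the reference gene table. Probe sets of a gene were averaged, which concerned 55 of 19505 genes. No filter and no further normalization was applied.

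The supernatant and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, trend and robust off), with Benjamini-Hochberg adjustment over 19505 genes and a threshold of 0.05. The design, 39 gene lists with 727 measured of 815 listed members, the alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 39 lists, with an estimated correlation and fry as alternatives; members were counted past the threshold over all genes and adjusted over the list alone. The rule names the 15 largest changes per direction among genes past the threshold with groups that do not overlap; from each list up to 6 members past the threshold over all genes, else over the list alone, else up to 3 with the largest change, given as values; and 10 genes whatever their values. As 0 genes passed over all genes, the largest changes were taken from the fit with the replicate term. That fit was foreseen; its use for this purpose, and the 3 lists of imprinted genes, ERK targets and histones were chosen after the data were examined.

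The scripts were tested on simulated data: 20 simulations of 19505 genes with 200 changed genes for the comparison of supernatant and control. Without the term, changes of 1, 2, 3 and 4 (log2) were recovered in 0.2%, 7.8%, 75.0% and 94.6% of cases, with 0.424% false calls; with the term, in 5.1%, 90.4%, 99.2% and 100% of cases, with 9.84% false calls. A list of 25 genes raised by 1 was found in 100% of simulations with the preset correlation, 0% with the estimated correlation and 20% with fry. The simulated noise was independent between genes, and the simulated values were not rounded to 2 decimals as the deposited ones are.

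Alternatives were median centring, quantile normalization, filters at the 25th percentile and at the median of mean expression, the replicate number as a block (the replicate term), a trended and a robust prior, the highest probe set per gene, all probe sets, a minimum change of 1, an adjusted p of 0.1, and leaving out each array. Added after the data were examined were the fit with the replicate term under these settings, the same fit without genes of zero residual variance, and the same fit after noise of the size of the rounding was added in 5 draws. The precision of single values is limited by the 2 arrays per group.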

Results

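Expression was measured in mouse peritoneal macrophages, phagocytes of the abdominal cavity, with and without exposure to supernatant derived from necrotic cells. The sample titles call the cells PEC. The source and killing of the necrotic cells were not given in the sources used here. The series holds 4 arrays of wild-type cells: 2 control arrays and 2 arrays of cells kept with the supernatant for 2 h. No time was recorded here for the controls, so effects of handling and of the supernatant cannot be told apart. The array covers the transcriptome in 22206 probe sets, of which 19572 carry 1 gene symbol, and these gave 19505 genes. The median log2 value lay between 5.16 and 5.25 on the 4 arrays. The number of arrays, 2 per group, limits the precision of every value given here.

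The arrays of 1 group correlated across genes with Pearson's r of 0.989 for the controls and 0.985 for the supernatant arrays. Arrays of different groups with the same replicate number correlated as closely, with r of 0.987 and 0.989. The Y-linked genes Uty, Eif2s3y and Kdm5d separated the replicate numbers in both groups. Uty was at 10.65 in the control and 10.10 in the supernatant array of replicate 1, and its mean difference between replicate 2 and replicate 1 was -7.52 (log2). Replicate 1 thus came from cells with Y-linked transcripts and replicate 2 from cells nearly without them. For this reason each change is also given within each replicate number, and a second fit holds a term for the replicate number (the replicate term). This term was foreseen before the data were examined, and giving its results beside those without it was decided afterwards.

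The comparison addresses which transcripts differ in the RNA of macrophages after contact with material released by dead cells. RNA carried over from the necrotic cells could add to such differences, and this was tested only for cell cycle and inflammatory genes. The largest differences were increases. Peg10, an imprinted gene derived from a retrotransposon, was at 3.85 ± 0.50 in the controls and 10.34 ± 1.47 in the supernatant arrays (log2, mean ± SD, n = 2 each). Bcat1, an aminotransferase of branched-chain amino acids, was at 4.93 ± 0.25 and 11.03 ± 1.10. Serpinb2, a plasminogen activator inhibitor that activated macrophages make, was at 7.45 ± 0.34 and 11.73 ± 0.40. Among the genes called lower below, the changes were -2.83 for Rnf144b, -2.45 for Fbxo32 and -1.94 for Trp53inp1; Fbxo32 encodes a ubiquitin ligase subunit and Trp53inp1 a target of p53.

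In the limma fit without the replicate term, 0 genes were higher and 0 were lower at an adjusted p under 0.05, and the smallest adjusted p was 0.0590. At an unadjusted p under 0.05, 740 genes were higher and 500 lower, 6.36% of the genes, and camera and fry are the other tools run, on gene lists. At an adjusted p under 0.1, 32 genes were higher and 1 was lower. The groups did not overlap for 34.0% of the genes, where chance gives 33.3% if the arrays are interchangeable. They were not, as the differences of the replicates correlated between the groups across genes (r = 0.464). The comparison with 33.3% thus does not show whether there was an excess. A change of at least 1 in both replicate numbers was seen for 272 genes upward and 63 downward.

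With the replicate term, limma called 90 genes higher and 3 lower at an adjusted p under 0.05. The 15 largest increases among them were those of Peg10, Bcat1, Gstm5, Mir675, Serpinb2, Sinhcaf, Prkg2, Schip1, H2bc18, Cks1b, Spred2, H4c6, Phlda1, Ube2c and Psma5, with differences of 6.49 for Peg10 and 3.16 for Psma5. The control values of Peg10, 4.21 and 3.50, lie near the lower quartile of the arrays (3.52 to 3.62), and the control means of Bcat1, Mir675, Prkg2, Schip1 and Phlda1 also lie below the array medians; detection was not analysed here, so these are differences between deposited values and not measured folds of transcript. Mir675 is the symbol annotated to its probe set, and whether that probe set reads a microRNA or a longer transcript was not tested. The change of Peg10 was 7.17 in replicate 1 and 5.80 in replicate 2, and that of Serpinb2 was 3.76 and 4.80. This count is not stable: with the unnamed probe sets added it was 0 and 0, with a smallest adjusted p of 0.0575, and with a trended prior it was 436 higher and 241 lower. The fit has 1 residual degree of freedom, and on simulated changes 9.84% of its calls were false. The simulated values were not rounded to 2 decimals as the deposited ones are, so this share is not an error rate for these calls. Below, "rose" and "fell" are used of lists past the threshold of camera and of genes past the threshold in the fit without the term when adjusted over the list alone, or in the fit with the term.

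**Figure D1:**
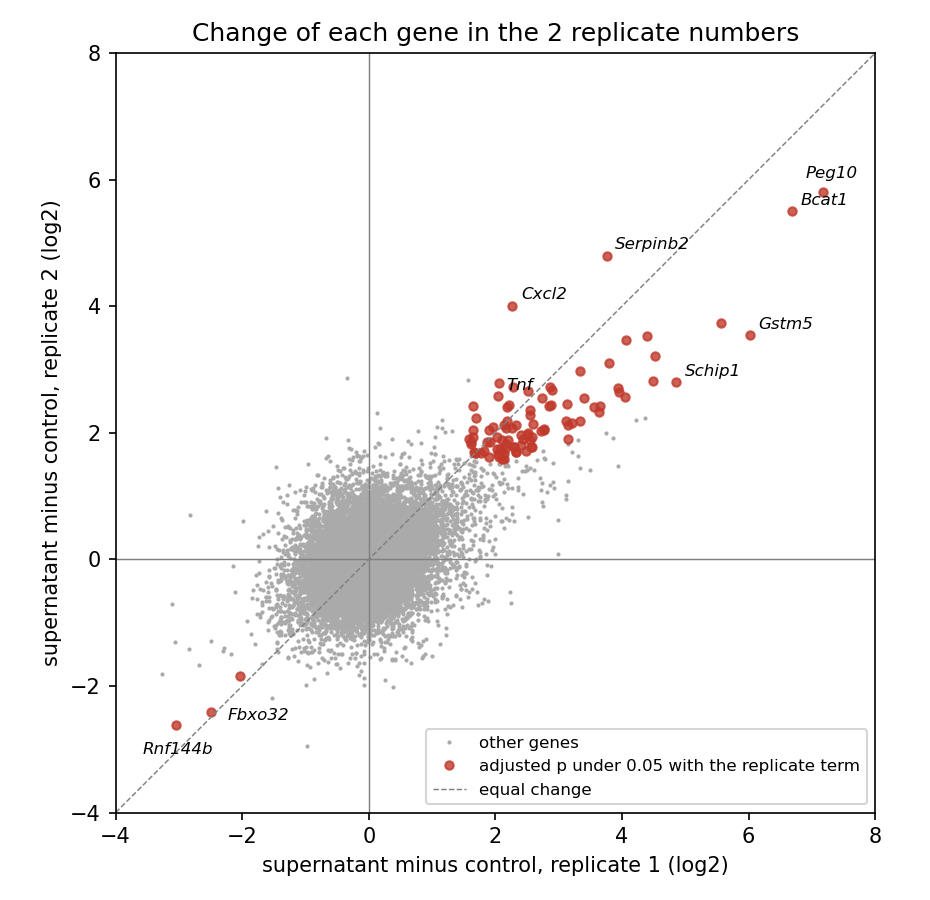
Each point is 1 gene, with its change (supernatant minus control, log2) in replicate 1 on the horizontal and in replicate 2 on the vertical axis; red points had an adjusted p under 0.05 with the replicate term. The 90 red points that are higher lie at a positive change in both replicate numbers, and the 3 that are lower at a negative change in both.

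Tnf and Il1b rose among the inflammatory cytokines. Tnf, a cytokine central to acute inflammation, went from 6.36 ± 0.61 to 8.67 ± 0.23, and Il1b, the precursor of interleukin-1 beta, from 4.98 ± 0.06 to 6.83 ± 0.32 (log2, mean ± SD, n = 2 each). Of 20 inflammatory cytokines measured, 2 rose when adjusted over the list alone and 0 passed over all genes without the replicate term. There limma's adjusted p over all genes was 0.145 for Tnf and 0.148 for Il1b. With the term both passed over all genes (limma adjusted p = 0.0348 and 0.0457), in the fit whose count was not stable. Camera called the list higher (median change 0.19, adjusted p = 0.0469; adjusted p = 0.741 with an estimated correlation), but not with the replicate term (adjusted p = 0.114), and its median was -0.015 among genes above the 25th percentile of expression. The median was 0.06 in replicate 1 and 0.38 in replicate 2, and the call was lost without control replicate 1 (median 0.17) and without supernatant replicate 2 (median 0.0075), while the median was 0.39 without supernatant replicate 1. Il6 was at 2.71 ± 0.02 and 3.59 ± 0.44, Ifnb1 at 4.21 ± 0.50 and 3.93 ± 0.18, and Il10 at 4.98 ± 0.49 and 4.83 ± 0.63, and none of these 3 passed in either fit.

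Chemokines attract leukocytes. Of 18 CC and other chemokines, 2 rose when adjusted over the list alone: Ccl24, an attractant of eosinophils, by 3.21 ± 0.48 (SE) and Ccl2, an attractant of monocytes, by 2.43 ± 0.37. The list was higher (median 0.29, camera adjusted p = 0.00951; adjusted p = 0.692 with an estimated correlation). Its median was 0.11 without control replicate 1, 0.44 without supernatant replicate 1 and 0.15 without supernatant replicate 2, where the call was lost. With the replicate term, Cxcl14, Ccl9 and Ccl7 also passed over the list alone, for a count of 5. Of the 6 CXC chemokines that attract neutrophils, Cxcl2 rose by 3.14 ± 0.58, with changes of 2.27 and 4.01 in the 2 replicate numbers, while the change of Cxcl1 was 0.30 ± 0.29, with 0.04 and 0.56 in the 2 replicate numbers, and did not pass; the list itself did not pass (camera adjusted p = 0.127). Among 13 chemoattractant receptors, Ccr1 rose by 1.70 ± 0.36 and Cxcr4 fell by 2.13 ± 0.45, and the list did not pass (camera adjusted p = 0.874). Of 23 genes of the NF-kB pathway and its feedback, Tnip3, an inhibitor of NF-kB signalling, rose by 2.19 ± 0.28 when adjusted over the list alone; the list was higher (median 0.40, camera adjusted p = 0.00787; adjusted p = 0.741 with an estimated correlation). That call was lost without control replicate 1 (median 0.27) and without supernatant replicate 2 (median 0.23). With the replicate term 9 members passed over the list alone, among them Nfkbia at 1.61, Zc3h12a at 1.12 and Tnfaip3 at 0.92. Among 32 pattern recognition receptors, Clec4e, which binds material of dead cells, rose by 2.05 ± 0.37 and Cd14 by 1.39 ± 0.29, with a list median of -0.07 that did not pass (camera adjusted p = 0.759). Among 21 inflammasome and purinergic genes Il1b passed over the list alone without the replicate term; with the term 2 were higher, Il1b and Nlrp3 (0.80), and 4 lower, P2ry13 (-1.03), P2rx7 (-0.94), Nlrp1b (-0.91) and Aim2 (-0.88). The list did not pass (camera adjusted p = 0.359).

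**Figure D2:**
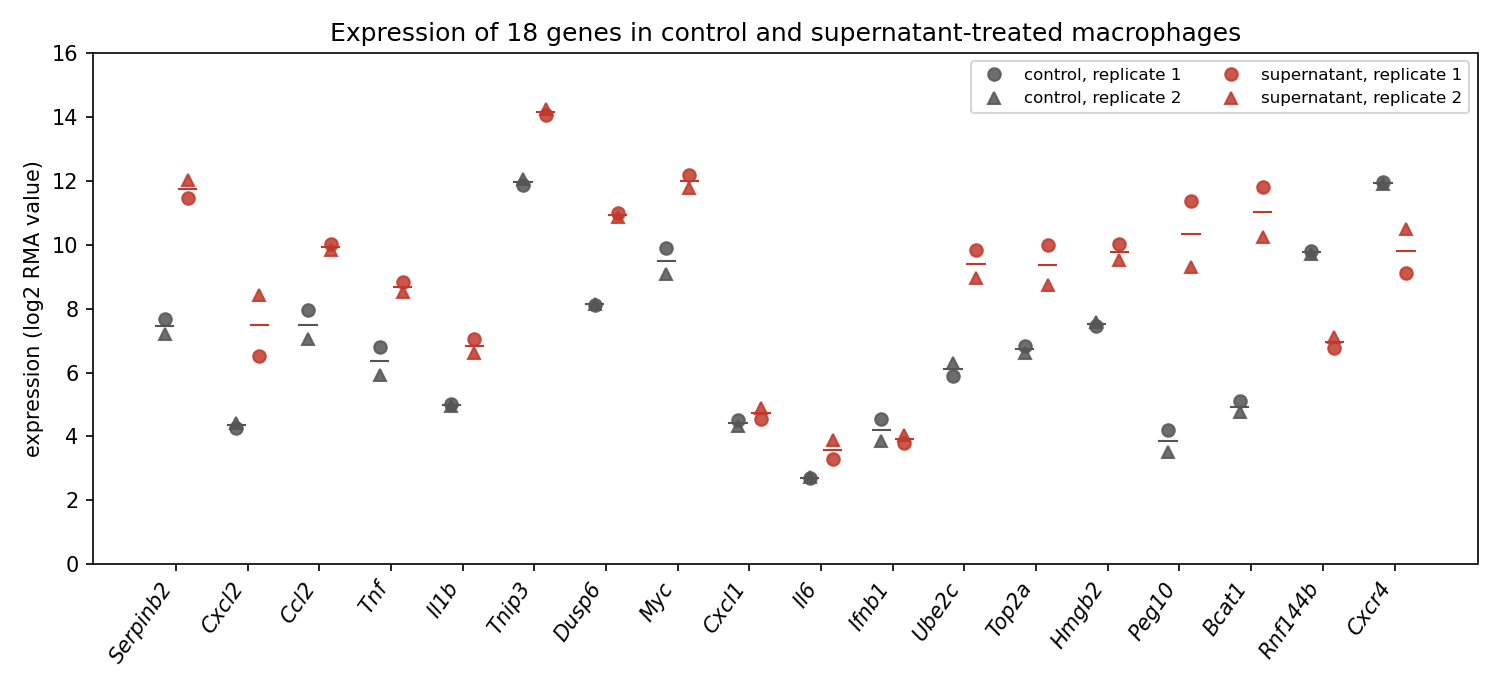
Log2 expression of 18 named genes on each of the 4 arrays, with control in grey, supernatant in red, circles for replicate 1, triangles for replicate 2 and short lines for group means. Serpinb2, Tnf, Il1b, Peg10 and Bcat1 lie higher on both supernatant arrays than on both control arrays, and Rnf144b and Cxcr4 lower.

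Immediate early genes, which are transcribed within minutes of a stimulus, rose as a list with camera (adjusted p = 7.14e-07; adjusted p = 0.692 with an estimated correlation). Of 36 measured, 9 rose when adjusted over the list alone and 0 passed over all genes. Dusp6, a phosphatase that dampens ERK, rose by 2.79 ± 0.27 (SE), Phlda1 by 3.31 ± 0.39, the transcription factor Myc by 2.50 ± 0.37, Dusp4 by 2.33 ± 0.46, the nuclear receptor Nr4a3 by 2.04 ± 0.31 and Dusp5 by 1.74 ± 0.31 (n = 2 per group). The median change of the list was 0.33, with 0.36 in replicate 1 and 0.36 in replicate 2. Without control replicate 1 the count of 9 fell to 4, and the median was 0.15 there and 0.21 without supernatant replicate 2; camera kept the call whichever array was left out. With the replicate term 14 members passed over the list alone and 6 over all genes. The 20 cAMP and CREB targets were higher (median 0.56, camera adjusted p = 0.00509; adjusted p = 0.692 with an estimated correlation), and Nr4a3 was their member past the threshold without the replicate term. With the term 4 passed over the list alone: Nr4a3, Pde4b, Fosl2 and Dusp1. Camera lost the call without control replicate 1 (median 0.20) and without supernatant replicate 2 (median 0.14).

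Cell cycle genes rose together, and this was the list with the smallest camera p of the 39 (adjusted p = 2.87e-19; adjusted p = 0.692 with an estimated correlation). All 27 measured members had a change above 0, with a median of 1.20, and the median was 1.14 in replicate 1 and 1.19 in replicate 2. Adjusted over the list alone, 11 members rose, and 0 passed over all genes. Ube2c, which acts in mitotic exit, rose by 3.30 ± 0.38 (SE), the topoisomerase Top2a by 2.63 ± 0.43, the mitotic kinase Aurkb by 2.23 ± 0.59 and Cenpf, Birc5 and Tpx2 by 2.17, 1.96 and 1.87. The change of Aurkb was 1.42 without supernatant replicate 1. The count of 11 was 3 without control replicate 2, 6 without supernatant replicate 1 and 18 without supernatant replicate 2; the median was 0.76 without control replicate 2, and camera kept the call whichever array was left out. With the replicate term 22 members passed over the list alone and 7 over all genes. The median difference of the list between replicate 2 and replicate 1, over both groups, was -0.71 (camera adjusted p = 2.87e-08; adjusted p = 0.599 with an estimated correlation).

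Stress and repair lists were higher as well. Among 31 genes of wound repair, adhesion and proteolysis, Serpinb2 rose by 4.28 ± 0.33 (SE), Tgfbi, a matrix protein, by 2.60 ± 0.39 and Timp1, an inhibitor of matrix proteases, by 1.86 ± 0.34 (list median 0.21, camera adjusted p = 0.00128; adjusted p = 0.692 with an estimated correlation). Among 25 NRF2 and oxidative stress genes, Me1 rose by 2.41 ± 0.45 (list median 0.22, camera adjusted p = 0.0113; adjusted p = 0.692 with an estimated correlation), and among 14 heat shock proteins Hspb8 rose by 1.95 ± 0.30 (list median 0.28, camera adjusted p = 0.0215; adjusted p = 0.741 with an estimated correlation). The call of wound repair was lost without control replicate 1 (median 0.15) and without supernatant replicate 2 (0.13), with a median of 0.35 without control replicate 2 and 0.50 without supernatant replicate 1. Those of NRF2 and of heat shock were lost without control replicate 2 (medians 0.15 and 0.29) and without supernatant replicate 1 (0.28 and 0.17); the NRF2 median was 0.12 without control replicate 1 and 0.52 without supernatant replicate 2. With the replicate term 6 genes of wound repair and 7 of NRF2 passed over the list alone, the latter with Mt2 at 1.28, Txnrd1 at 1.13 and Slc7a11 at 1.12. The 36 cytosolic ribosomal proteins had a median of 0.20 (camera adjusted p = 0.00951; adjusted p = 0.735 with an estimated correlation), and the largest change, 1.04 for Rps20, did not pass; the call was lost without control replicate 1 (median 0.0975) and without supernatant replicate 2 (median 0.16), and the median was 0.30 without control replicate 2. Mthfd2, of mitochondrial folate metabolism, and the amino acid transporter Slc7a5 rose by 2.17 and 2.00 among 29 genes of the unfolded protein and integrated stress response, whose list did not pass (camera adjusted p = 0.761).

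Of 18 alarmins and proteins of dying cells, Hmgb2 rose by 2.26 ± 0.31 (SE), Hdgf by 1.49 ± 0.30 and Il33 by 1.29 ± 0.29. The list was higher (median 0.07, camera adjusted p = 0.0344; adjusted p = 0.692 with an estimated correlation) but not with the replicate term (adjusted p = 0.0550), and the call was lost whichever array was left out, with medians of 0.25 without control replicate 1, 0.13 without control replicate 2, 0.085 without supernatant replicate 1 and 0.14 without supernatant replicate 2. Hmgb1, a nuclear protein that acts as an alarmin outside cells, changed from 14.84 ± 0.26 to 15.56 ± 0.43 without passing, and Tpt1, the translationally controlled tumour protein, was at 17.15 ± 0.51 and 16.94 ± 0.11 and did not pass. Of 16 glucocorticoid targets, Errfi1, Fkbp5 and Nfkbia rose by 2.11, 1.91 and 1.61, with 1.04 for Nfkbia without supernatant replicate 2 (list median 0.18, camera adjusted p = 0.0426; adjusted p = 0.741 with an estimated correlation; adjusted p = 0.0550 with the replicate term). The call was lost without control replicate 1 (median 0.14) and without supernatant replicate 2 (median 0.02), and the median was 0.29 without control replicate 2 and 0.44 without supernatant replicate 1. With the term 5 passed as higher over the list alone, with Mt2 and Dusp1 added, and Tsc22d3 passed as lower at -1.09.

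**Figure D3:**
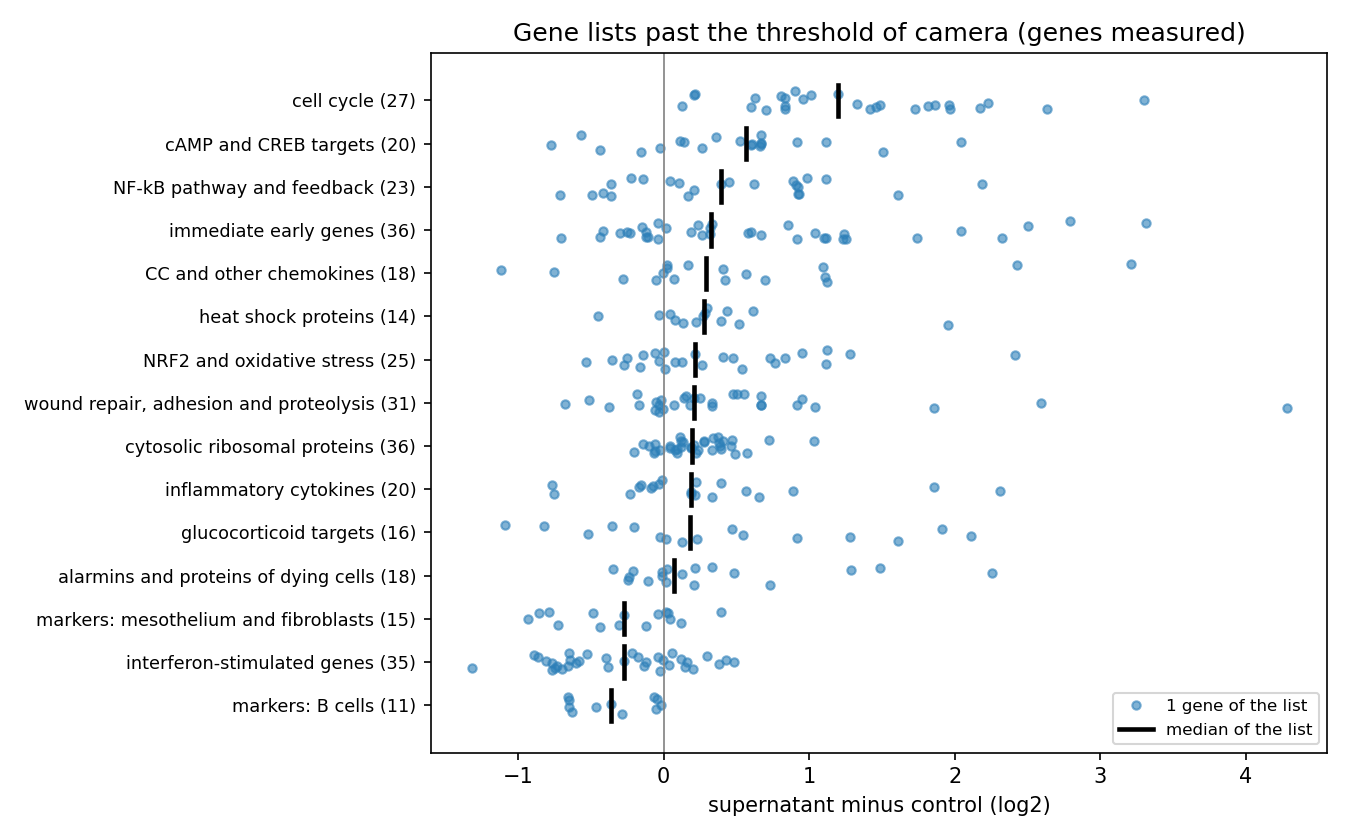
Change (supernatant minus control, log2) of each gene in the 15 lists past the threshold of camera, with 1 point per gene and a black line at the list's median; the number measured stands in brackets. The cell cycle list has all 27 points above 0, and the 11 B cell markers lie below 0.

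Of the lists past the threshold, 3 were lower. The 35 interferon-stimulated genes had a median change of -0.28, with -0.33 in replicate 1 and -0.35 in replicate 2 (camera adjusted p = 0.00951; adjusted p = 0.757 with an estimated correlation), and 0 members passed, with Irf7 at -1.32, Tnfsf10 at -0.89 and Usp18 at -0.87. Leaving out 1 array at a time gave -2.87 to 0.23 for Irf7, which thus turned direction, -1.38 to -0.41 for Tnfsf10 and -1.49 to -0.25 for Usp18. That call was lost without control replicate 2 (median -0.01) and without supernatant replicate 1 (-0.15), and the median was -0.56 without control replicate 1 and -0.59 without supernatant replicate 2. The 11 B cell markers had a median of -0.37, with 0 above 0 (camera adjusted p = 0.0198; adjusted p = 0.757 with an estimated correlation), and the 15 markers of mesothelium and fibroblasts a median of -0.27 (camera adjusted p = 0.0469; adjusted p = 0.742 with an estimated correlation). Both marker calls were lost without control replicate 2, with medians of -0.19 for B cells and 0.04 for mesothelium and fibroblasts, and without supernatant replicate 1, with medians of -0.09 and -0.07. The B cell median was -0.69 without supernatant replicate 2, and the mesothelium and fibroblast median was -0.41 without control replicate 1. In both marker lists 0 members passed. Of the neutrophil markers, Csf3r fell by 1.41 ± 0.31 (SE) when adjusted over the list alone, while the list of 13 did not pass (camera adjusted p = 0.115).

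The remaining lists did not pass with camera. Their median changes were -0.11 for eicosanoid synthesis, where Ptgs2 was at 0.66, -0.04 for hypoxia and glycolysis, -0.05 for uptake of dead cells and lipid efflux, 0.08 for cholesterol synthesis, -0.03 for alternative activation, -0.11 for antigen presentation and costimulation, -0.03 for iron and acute phase, 0.08 for cell death regulators and 0.08 for oxidative phosphorylation. Among markers they were -0.04 for macrophages in general, -0.17 for large resident peritoneal macrophages, -0.10 for small peritoneal macrophages and monocytes, -0.02 for T and NK cells, 0.10 for mast cells and eosinophils, 0.23 for dendritic cells, -0.09 for epithelium, -0.19 for red blood cells and -0.06 for sex-linked genes. Camera with a preset correlation called 15 of the 39 lists, 12 of them higher and 3 lower, and 12 of the 15 held with the replicate term. With an estimated correlation or with fry, whose lowest adjusted p was 0.415, 0 of 39 passed. In simulations with noise independent between genes, these tests found a list raised by 1 in 0% and 20% of cases, so they had little power there. In the data, the estimated correlation over the called lists ran from -0.0551 (CC and other chemokines) to 0.784 (B cell markers). It was 0.499 for cell cycle. The simulations did not cover such correlation, so low power alone is not shown to explain the failure. The same camera between the replicate numbers called lists too, with an adjusted p of 1.37e-25 for hypoxia and glycolysis. Cell cycle, immediate early, NF-kB, cAMP, interferon-stimulated, wound repair, B cell and mesothelium and fibroblast lists were among them. A small camera p alone thus does not mark an effect of the supernatant. Without supernatant replicate 2, 8 lists passed. Of the 15 lists, 2 kept the call whichever array was left out, cell cycle and immediate early genes. In other lists that camera did not call, further members that passed over the list alone with the replicate term, and not without it, were Asns, Egln3, Clec2d, Il4ra, Tgm2, Cd209b, Mertk and Hdc, named after their values were seen.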

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

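The settings of the fit with the replicate term, among them those without zero-variance genes and with rounding noise, were chosen after the data were examined; the other settings were fixed before, and following the counts of cell cycle and immediate early members through them was decided after. Without the term, the counts of 0 higher and 0 lower became 2 higher with a trended prior and 32 and 1 at an adjusted p of 0.1; leaving out each array in turn gave 0 to 4 higher. Differences of the replicates correlated between the groups across genes (r = 0.464), genes not being independent replicates. With the replicate number as a block (the replicate term), 90 genes were higher and 3 lower, and 22 cell cycle and 14 immediate early members rose over the list alone.

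The counts of 90 and 3 with the term depended on the setting: 6 were lower with median centring; 277 and 74 were higher and lower with quantile normalization, 186 and 51 among genes above the median of mean expression, 436 and 241 with a trended prior, 159 and 18 at an adjusted p of 0.1, 0 and 0 with all probe sets, 513 and 256 without the 153 genes of zero residual variance, and 283 and 76 (median of 5 draws) with rounding noise, where the draws gave 258 to 311 and 53 to 97 and called all 93 genes again in each. With all probe sets 90 of the 93 had an adjusted p under 0.1. The prior degrees of freedom were 5.29 for named genes and 4.42 with all probe sets; the cause of the differences in count was not tested. Leaving out an array leaves this fit no residual degrees of freedom, so it was not run.

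Gene lists past the threshold numbered 15, 0 with an estimated correlation and 0 with fry, and 8 to 12 when each array was left out; of the 15, 2 kept the call in all 4 cases, 1 in 3, 11 in 2 and 1 in 0. Calls were also gained: hypoxia and glycolysis passed in each case, lower without control replicate 1 (median -0.66) and supernatant replicate 2 (-0.75), higher without control replicate 2 (0.92) and supernatant replicate 1 (0.85); neutrophil markers without control replicate 1 (-0.23), mast cell and eosinophil (0.38) and sex-linked (-3.58) markers without control replicate 2, and CXC chemokines without supernatant replicate 1 (0.36). Cell cycle members over the list alone numbered 3 to 18 and immediate early members 4 to 9 when each array was left out. The mean correlation of replicates was 0.984 among genes above the 25th percentile and 0.976 among genes above the median, as these filters leave out genes of low mean value. At the 25th percentile the medians changed sign for inflammatory cytokines (-0.015), hypoxia and glycolysis (0.0725) and T and NK cells (0.035); at the median filter for inflammatory cytokines (-0.035), hypoxia and glycolysis (0.0725), pattern recognition receptors (0.025), alternative activation (0.26) and dendritic cells (-0.0925); the cause was not tested. A list's direction here is the sign of its median, a choice made after the data were examined, since camera's direction differed from it for some lists.

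Signs also changed when an array was left out, with 1 array then assumed to vary like the other group. The ranges of changes were Egln3 -0.36 to 3.63, Eif2s3y -3.84 to 3.72, Hpgd -1.86 to 0.10, Ifnb1 -0.63 to 0.08, Retnla -1.54 to 0.28, Uty -4.15 to 3.68, Vegfa -0.61 to 1.95, Vsig4 -1.60 to 0.13, Idi1 -0.10 to 0.87, Il10 -0.60 to 0.29, Irf7 -2.87 to 0.23, Kdm5d -2.54 to 3.12, Ndrg1 -2.92 to 0.73, Tpt1 -0.57 to 0.15, Tspo2 -0.66 to 0.26, Ccr3 -0.35 to 1.91. The ranges of list medians were oxidative phosphorylation -0.11 to 0.17, small peritoneal macrophages and monocytes -0.12 to 0.0325, sex-linked genes -3.84 to 3.46, chemoattractant receptors -0.16 to 0.36, eicosanoid synthesis -0.23 to 0.26, hypoxia and glycolysis -0.75 to 0.92, pattern recognition receptors -0.22 to 0.0425, cholesterol synthesis -0.19 to 0.11, alternative activation -0.21 to 0.26, antigen presentation and costimulation -0.50 to 0.28, macrophages in general -0.21 to 0.06, mesothelium and fibroblasts -0.41 to 0.04, unfolded protein and integrated stress response -0.11 to 0.06, neutrophils -0.25 to 0.04, mast cells and eosinophils -0.0375 to 0.38. The cause was not tested, except that leaving out an array leaves its group with 1 replicate number only. Genes that differ between the numbers then move for that reason, among them the sex-linked genes. The mean difference between replicate 2 and replicate 1 was 3.54 for Egln3, and the median for hypoxia and glycolysis was 1.91. Of the other results for named genes, 988 kept their direction and side of the threshold and 41 passed it newly under settings that keep every array. As 0 genes passed in the fit without the replicate term, a kept side here means that the gene still did not pass. For lists 344 kept both and 38 lost the threshold. These losses include every called list with an estimated correlation and with fry. Camera was not rerun with a robust prior, which it does not use. Without a change of sign, leaving out 1 array gave 0.14 to 0.46 for Cxcl1, 0.43 to 0.90 for Ptgs2 and 0.43 to 1.04 for Hmgb1. Medians were then 0.035 to 0.23 for dendritic cells, -0.18 to -0.04 for epithelium and -0.31 to -0.11 for red blood cells. They were -0.18 to -0.04 for iron and acute phase, 0 to 0.23 for cell death regulators and -0.0425 to -0.0075 for T and NK cells. That of uptake of dead cells and lipid efflux was -0.105 to -0.005. Signal over background was not analysed here, so low values such as those of Il6 limit what can be seen.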

Other observations

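The lists and tests of this part were chosen after the data were examined, except that the tests of carried-over RNA and of 1 RNA source had bounds written before their values were seen. Of 19 feedback and target genes of ERK, the kinase that growth factors and danger signals activate, 18 had a change above 0, with a median of 2.33, and 13 passed in limma with the replicate term, while 0 passed without it. Spred2, an inhibitor of Ras signalling, changed by 3.45, Etv4 and Etv5, transcription factors downstream of ERK, by 2.79 and 2.66, and Spred1 by 2.41. The list was written after Dusp6 and Spred2 had been seen among the largest changes, so its count is not independent evidence.

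Of 53 histone genes of the replication-dependent clusters, 51 had a change above 0, with a median of 1.47, and 10 passed with the replicate term while 0 passed without it. H3c13, H3c14 and H3c15 are near-identical copies, and their values are uncertain as to which copy they measure. Of 19 imprinted genes, 3 passed with the replicate term: Peg10, Peg3 at 2.38 and the probe set named Mir675 at 4.66, whose transcript was not resolved. The median of that list was 0.16, and Igf2 was at 0.16. Whether carried-over RNA lies behind the histone and imprinted genes was not tested.

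The first pattern is the higher cell cycle list. A shift by normalization that genes of like mean value share is argued against. The median of the list was 1.20, and the highest median among 10000 random lists matched on mean value was 0.37. The median of the random medians was -0.045. The list was picked for its small camera p and its members vary together (estimated correlation 0.499), so this is no measure of chance. A shift particular to these genes was not tested. A lower share of macrophages, with all 8 listed other cell types rising alike, is argued against too. The highest median among their marker lists was 0.23 against 1.20, with an SD over cell cycle members of 0.77. The median of the general macrophage markers was -0.04. A rise of 1 dividing cell type, or of a type without a list, was not tested. Some marker lists also had low values, with a control median of 3.84 for T and NK cells. RNA of the necrotic cells carried over into the macrophage RNA cannot be told apart from a response of the macrophages. The log2 ratio of the linear rises in the 2 replicate numbers had an SD of 0.309 over 7 called members, below 0.489. That 0.489 is the SD that array noise gives to the difference of the 2 log2 changes. The ratio of linear rises is another quantity, so the comparison decides nothing. The 7 members were also selected for like changes in both numbers. Over the 12 members that rose by at least 1 in both numbers the SD was 0.507. The rule by which this test could have come out in favour of carry-over was set after its values were seen, and a response of the macrophages stays open as well.

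The second pattern is that inflammatory and cell cycle genes were called together. If 1 carried-over RNA source had raised both, the log2 ratio of the linear rises in replicate 1 to those in replicate 2 would be alike. The median was 1.24 over 7 cell cycle genes and -0.09 over 6 inflammatory genes, a difference of 1.33 (exact permutation test over genes, two-sided, 1716 permutations, p = 0.00583). The bound written beforehand was wrong for these genes, since their calls favour like log2 changes in both numbers, which ties the ratio to the baseline difference between the arrays, and an unknown rescaling of the values would change the linear rises. In wider sets, chosen afterwards, the difference was 0.93 (permutation p = 0.0564) over 15 cell cycle and 13 inflammatory genes with a mean change of at least 1, and 1.53 (permutation p = 0.00046) over 21 and 21 with at least 0.75. So 1 source for both sets cannot be told apart from separate ones.

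The third pattern is the split of arrays by replicate number. The smallest gap between the numbers over Uty, Eif2s3y and Kdm5d was 5.37, which animals of opposite sex would give, but these genes prompted the explanation. Xist and Ddx3y, also among the 5 sex-linked genes listed, were not measured under their names, so Xist could not be used here. Eif2s3x, Kdm6a, Kdm5c and Ddx3x escape X inactivation and were chosen after the data were examined. Their median difference was 0.06 between replicate 2 and replicate 1. With the genes measured, opposite sex, a mixed replicate 1 and a lost Y chromosome cannot be told apart. Beside Uty, Eif2s3y and Kdm5d, 28 genes were higher and 7 lower in replicate 2. The hypoxia and glycolysis list had a median difference of 1.91, with 10 members called higher. Arg1 was at 12.42 in the control of replicate 1 and 16.94 in that of replicate 2. Whether sex or another difference between the numbers lies behind the hypoxia list cannot be told apart, because arrays with and without Y-linked transcripts never share a number.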
